A study of Arabidopsis with 4 samples.

How the data were processed

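Transcript levels were measured by RNA sequencing in 4 libraries of whole Arabidopsis seedlings, 2 from the wild type Col-0 and 2 from the mutant jmj28-2. Per the labels' protocols, seedlings were 12 days old and had grown on medium with 1% sucrose at 23 °C, with 16 h of light and 8 h of dark per day. Genotype and replicate number of each library were taken from its label, and each column of the table was matched to a library by its name, with 0 columns of samples left unmatched.

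The authors deposited 1 table with a value per gene and library, rounded to 2 decimals. Although the table is labelled as FPKM, its 4 columns sum to 999011, 998993, 998943 and 999014, as TPM (transcript abundance scaled to a fixed total per library) do and FPKM do not, so the deposited values were treated as TPM. The planned design had assumed FPKM; the test is the same for both units, and FPKM in the plan was read as TPM. Per the submitters' processing notes, TopHat, RSEM and edgeR were used with the genome build TAIR10, and no versions are named there. Filters, the annotation version and whether strand was used in counting are not given in the sources used here. TPM keep no record of sequencing depth, so the depth of each library is unknown and no counting interval or detection floor is given. TPM also share a fixed total, so a large rise of abundant transcripts lowers the values of all others. Reads from near-identical genes, such as the light-harvesting, Rubisco small-subunit and receptor-like kinase families, are divided among copies by estimation, and values of their single members are uncertain. The same holds for overlapping and antisense genes. An exact 0 can be a failed estimate, so such genes are described as listed at 0, with the value of each library and no fold change.

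Of the 32833 genes in the table, the 19764 with a mean of at least 1 TPM over the 4 libraries were tested. Values were transformed as log2(TPM + 1), and log2 changes below are on that scale, which understates changes of genes with low values. Each gene was fitted in limma 3.58.1 (R 4.3.3) with genotype as the only term and empirical Bayes moderation with an intensity trend, on 2 residual and 3.18 prior degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. A permutation of 2 libraries against 2 cannot give a two-sided p under 0.333. The labels do not say whether the 2 libraries of a genotype came from separately grown seedlings. The limma p-values of single genes therefore measure the spread between these libraries, which may be technical. The p-values of gene lists, described below, also rest on the spread between genes. The permutation p-values of the closing section move genes, not libraries. Figures were drawn with matplotlib 3.10.9.

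The 22 gene lists, holding 393 genes, were fixed from textbook knowledge before the data were examined, as were the tests of genes and lists, the rule for named genes and the alternatives, apart from those named at the end. AOP2 was not analysed here, which left 392 list genes. Lists with at least 3 tested members, 21 in all, were tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with all other genes tested, and adjusted over the lists. The seed storage list had 0 tested members. Camera with an estimated correlation, camera on ranks and fry were run as alternatives. Members of each list were also adjusted over the list alone.

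The rule for named genes takes JMJ28 and its family, CO, FT, SOC1 and FLC, up to 12 called genes per direction, and up to 4 members of each list with the smallest p. Genes outside that rule were chosen after their values were seen and are said to be so. Gene names come from the table, which names 13415 genes, and otherwise from a RefSeq gene table on assembly TAIR10.1, which matched 32548 of the 32833 identifiers. Because that assembly's name differs from the submitters' build, the RefSeq table served only for names and for the order of neighbouring genes, and no coordinates are given. JMJ28 is named B160 in the deposited table.

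The procedure was tested on simulated data, with 200 genes changed in each of 5 runs on 19764 genes for the comparison of jmj28-2 with Col-0. It called 79.8% of genes changed 2-fold and 98.2% of those changed 4-fold, with a mean of 11.6 false calls per run. Changes were planted only in genes at about 5 TPM or more, so these shares do not hold for lower genes. They also hold only for 200 changed genes. With fewer calls, such as the 15 in the real data, the adjustment is stricter, so a smaller share of changed genes may be called. A planted list was called in 5 of 5 runs, and 0 of 100 unchanged lists were called. Simulated genes varied independently and the lists were random. In the real lists the estimated correlation reached 0.77, for root markers. The simulation therefore cannot show how often lists of genes that vary together are falsely called.

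Alternatives covered the pseudocount, the filter, rescaling by median ratios, quantile normalization, moderation without the trend or with robust fitting, a replicate block, a 2-fold minimum and leaving out each library in turn. Leaving out genes listed at 0 throughout a genotype was added after the data were seen, as were 12 gene families taken from the deposited descriptions and most of the tests that weigh explanations, which the closing section names. Count-based tests and a comparison with the authors' own calls had been planned in case the table held them. They were not run, because it holds neither counts nor comparisons.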

Results

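Transcript levels of 32833 genes were compared between seedlings of the Arabidopsis wild type Col-0 (n = 2 libraries) and of jmj28-2 (n = 2 libraries), a mutant named for JMJ28, a JmjC-domain protein of the KDM3 group of histone demethylases. Col-0 is the standard laboratory accession. The comparison addresses which transcripts differ in 12-day-old seedlings when JMJ28 is mutated. Between 19606 and 19751 genes per library reached 1 TPM, and the 10 most abundant genes took 11.32% to 12.49% of each library. Across genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.9798 between the Col-0 libraries, 0.9772 between the jmj28-2 libraries and 0.9732 to 0.9759 between genotypes. Sequencing depth is unknown. Errors are standard deviations over n = 2 libraries unless a standard error (SE) is named.

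JMJ28 (AT4G21430, chromosome 4) had 7.63 and 7.70 TPM in Col-0 and 5.45 and 5.72 TPM in jmj28-2. The means were 7.67 ± 0.0495 and 5.59 ± 0.191 TPM, a mutant level of 0.729 times the wild-type level. Both jmj28-2 libraries lay below both Col-0 libraries, in the direction of their labels, but the difference did not pass over all genes (log2 change -0.40, SE 0.0963, limma adjusted p = 0.235) nor adjusted over the list alone (adjusted p = 0.0513). Where in the gene the mutation lies is not given in the sources used here, so the remaining signal does not show whether an intact transcript was made. Of the other 5 members of the family, JMJ29 had 9.52 ± 1.24 TPM in Col-0 and 8.07 ± 0.658 TPM in jmj28-2 (limma adjusted p = 0.51). JMJ24, JMJ27, IBM1 and JMJ26 had log2 changes between -0.0284 and 0.002, and the sign for JMJ26 turned under both rescalings. The family list did not pass (camera adjusted p = 0.133), and 0 of its 6 members passed adjusted over the list alone.

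In the same stretch of chromosome 4, the 4 genes on one side of JMJ28 in RefSeq order were listed at 0 in both jmj28-2 libraries and above 0 in both Col-0 libraries. CRK29 (AT4G21410), a cysteine-rich receptor-like kinase and the nearest of them, had 13.43 and 11.83 TPM in Col-0 and was listed at 0 in both jmj28-2 libraries (limma adjusted p = 0.00806). The other three were named after their values were seen. CRK28, of the same kinase family, had 3.59 and 3.12 TPM in Col-0 and did not pass (adjusted p = 0.089). SD18, another receptor-like kinase, had 2.14 and 2.45 TPM and did not pass (adjusted p = 0.142). B120, at 1.99 and 1.87 TPM, lay under the filter and did not pass without it (limma adjusted p = 0.0763). CRK28 passed under robust fitting (adjusted p = 0.0265) and, with SD18, without the trend (adjusted p = 0.0322 and 0.0445). The next gene out with a value above 0, the kinase gene AT4G21366, also named after its values were seen, was listed at 0 in both Col-0 libraries and at 1.23 and 1.11 TPM in jmj28-2. Further out on that side, and named after their values were seen, PUB8 had 7.48 and 7.84 TPM in Col-0 and 8.96 and 7.55 TPM in jmj28-2, and BHLH103 3.33 and 2.09 against 3.54 and 2.21 TPM. Beyond both, the subtilase gene ATSBT3.12 (AT4G21326) had 3.87 and 4.14 TPM in Col-0 and 0.78 and 0.89 TPM in jmj28-2, a ratio of 0.208 that passed under robust fitting (adjusted p = 0.0457) but not as reported (limma adjusted p = 0.109). Among the 10 nearest expressed genes on the opposite side of JMJ28, the ratio of the jmj28-2 mean to the Col-0 mean ran from 0.939 to 1.707. The call of CRK29 was lost with a pseudocount of 0.01 (adjusted p = 0.0867), without either Col-0 library (0.129 and 0.111) and without jmj28-2 replicate 1 (0.0588).

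**Figure D1:**
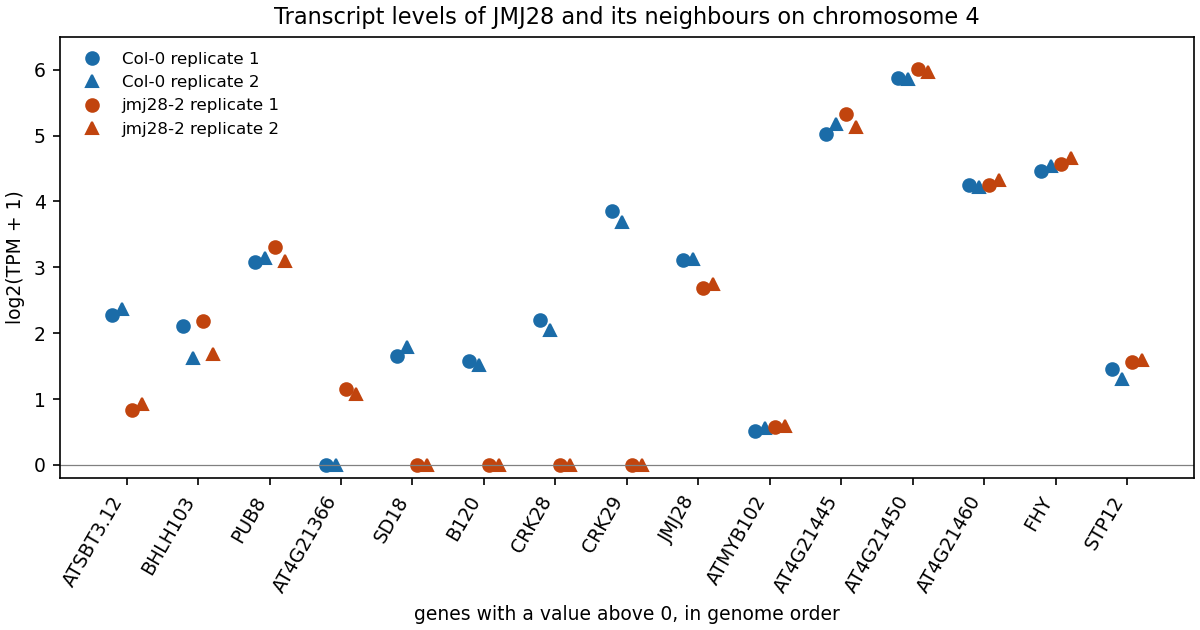
Transcript level, as log2(TPM + 1), of JMJ28 and neighbouring genes with a value above 0 in at least 1 library, in genome order on chromosome 4. Each point is 1 library, with Col-0 in blue and jmj28-2 in red. SD18, B120, CRK28 and CRK29 lie at 0 in both jmj28-2 libraries, while JMJ28 has 5.45 and 5.72 TPM there.

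Over all genes, 8 genes rose and 7 fell in jmj28-2 among the 19764 tested with limma. Of the 15, 5 were detected in both genotypes. ERF012 (AT1G21910), a transcription factor of the DREB subfamily, rose from 5.47 ± 0.382 to 16.1 ± 0.509 TPM, or 2.94-fold (log2 change 1.4, SE 0.0924, adjusted p = 0.0282). ASK4 (AT1G20140), a SKP1-like protein of the kind that joins F-box proteins to ubiquitin ligases, fell from 8.62 ± 0.339 to 1.41 ± 0.191 TPM, a Col-0 level 6.14 times that of jmj28-2 (log2 change -2.0, SE 0.131, adjusted p = 0.0282). AT1G09640, annotated as an elongation factor 1-gamma of translation, rose from 72.9 ± 0.0707 to 141.7 ± 3.60 TPM, or 1.94-fold (adjusted p = 0.0233). AT1G78830, annotated as an EP1-like glycoprotein, rose from 70.8 ± 2.2 to 131.7 ± 2.96 TPM, or 1.86-fold (adjusted p = 0.0282). AT3G01895, which has no description in the table, rose from 8.21 ± 0.856 to 22.6 ± 0.219 TPM (adjusted p = 0.0313).

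The other 10 called genes were listed at 0 throughout one genotype. The spliceosomal RNA gene U1.6 (AT3G01715) was listed at 0 in both Col-0 libraries and at 64.49 and 84.49 TPM in jmj28-2 (adjusted p = 0.00186). The U12 small nuclear RNA gene (AT1G61275), of the minor spliceosome, had 12.86 and 18.22 TPM in Col-0 and was listed at 0 in jmj28-2 (adjusted p = 0.0147). AT5G01017, AT5G00925 and AT4G39404 were listed at 0 in Col-0 and at 10.27 and 16.84, 10.13 and 11.77, and 4.78 and 4.42 TPM in jmj28-2. AT1G07847, AT2G08860, AT5G09855 and AT5G01005 were listed at 0 in jmj28-2 and at 18.66 and 30.4, 19.54 and 20.81, 12.56 and 8.51, and 5.21 and 4.93 TPM in Col-0. Genes listed at 0 in one pair of libraries and at 1 TPM or more in the other pair also occurred when libraries were paired across genotypes. There were 30 with the genotypes, and 30 and 27 in the other 2 pairings.

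The number of calls rested on few libraries. With all 4 libraries, robust fitting called 29 genes higher and 14 lower. Without Col-0 replicate 2, limma called 0 genes (1243 at an unadjusted p under 0.05). When Col-0 replicate 1, jmj28-2 replicate 1 or jmj28-2 replicate 2 was left out, 2, 2 and 3 of the 15 genes were still called, and with the genes listed at 0 throughout a genotype left out, 0 genes were called. At an unadjusted p under 0.05, limma found 2739 genes (1878 higher, 861 lower), where chance gives 988. The other 2 pairings of the libraries gave 409 and 408. In those pairings a genotype difference adds to the spread within pairs. Their counts can therefore fall below chance and are no baseline for the 2739.

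Among flowering-time genes, FLC (AT5G10140), the MADS-box repressor of flowering, had 2.88 ± 0.276 TPM in Col-0 and 9.05 ± 0.106 TPM in jmj28-2, a ratio of 3.15. SOC1 (AT2G45660), a floral integrator that FLC represses, had 32.1 ± 2.79 and 20.5 ± 2.55 TPM, a ratio of 0.638. Neither passed over all genes with limma, where FLC had a log2 change of 1.38 (SE 0.113, adjusted p = 0.065) and SOC1 one of -0.63 (SE 0.112, adjusted p = 0.195). Adjusted over the list alone, both passed (adjusted p = 0.00158 for FLC and 0.0282 for SOC1). Of the 37 genes fixed, 30 were tested, 12 with a higher and 18 with a lower mean. A total of 0 passed over all genes, and 3 higher and 4 lower passed adjusted over the list alone. TEM1, a repressor of FT, had 52.6 ± 13.9 and 95.3 ± 0.474 TPM (adjusted p = 0.0282 over the list alone). CDF3, of a family of DOF factors that repress CO, had 65.4 ± 1.41 and 50.1 ± 3.64 TPM (0.0282). The other three that passed there were named after their values were seen. TEM2 had 116.9 and 205.2 TPM, MAF3 19.1 and 14.5 TPM, and CDF1 18.7 and 14.7 TPM in Col-0 and jmj28-2. The photoperiod gene CO had 0.38 and 0.67 TPM in Col-0 and 0.37 and 0.55 TPM in jmj28-2, and its target FT 1.58 and 0.59 against 0.52 and 0.65 TPM. Both lay under the filter and were tested only without it, where neither passed (limma adjusted p = 0.899 for CO and 0.63 for FT). The list as a whole did not pass (camera adjusted p = 0.394), and FLC passed over all genes under robust fitting (adjusted p = 0.0234, range over its alternatives 0.0234 to 0.268).

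Among circadian clock genes, PRR5, a pseudo-response regulator, had 15.7 ± 0.247 TPM in Col-0 and 22.8 ± 0.0283 TPM in jmj28-2. The morning-phased PRR9 had 34.8 ± 0.0212 and 27.3 ± 0.332 TPM, and RVE8, an activator of evening genes, 16.8 ± 0.544 and 12.9 ± 0.686 TPM. These were the members that passed adjusted over the list alone (limma adjusted p = 0.012, 0.0241 and 0.0478), and 0 of the 21 tested passed over all genes. LNK2, a coactivator in the clock, had 199.7 ± 4.49 and 153.4 ± 20.4 TPM and did not pass (0.057). The list did not pass (camera adjusted p = 0.481).

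**Figure D2:**
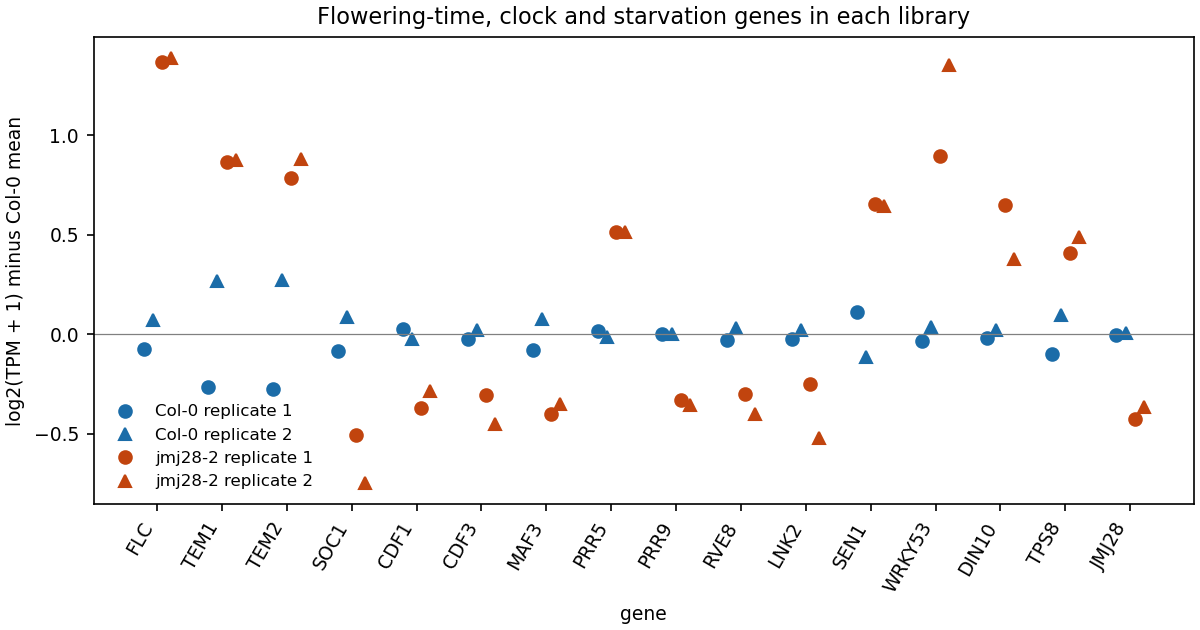
Log2(TPM + 1) of each library minus the mean of the Col-0 libraries, for named flowering-time, clock and carbon starvation genes and JMJ28. Each point is 1 library, with Col-0 in blue and jmj28-2 in red. FLC lies above the Col-0 mean in both jmj28-2 libraries (8.97 and 9.12 TPM) and SOC1 below it (22.29 and 18.69 TPM), and none of the genes shown passed over all genes tested.

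Genes of carbon starvation and senescence were higher in jmj28-2 as a group, with 12 of 13 tested members higher and a median log2 change of 0.42 (camera adjusted p = 0.000784; adjusted p = 0.828 with an estimated correlation). SEN1, a dark-induced gene, had 27.2 ± 3.13 TPM in Col-0 and 43.1 ± 0.226 TPM in jmj28-2. WRKY53, a regulator of leaf senescence, had 2.18 ± 0.106 and 6.0 ± 1.56 TPM, and the trehalose-phosphate synthase-like gene TPS8 27.4 ± 2.72 and 37.7 ± 1.54 TPM. With limma, 0 members passed over all genes and 6 passed adjusted over the list alone: SEN1, WRKY53, DIN10, TPS8 and, named after their values were seen, TPS11 and SEN4.

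Root marker genes were lower in jmj28-2 as a group (17 of 20 tested, median log2 change -0.25, camera adjusted p = 0.00476; adjusted p = 0.828 with an estimated correlation), but the difference sat in 1 library. The median of the list lay at 0.04 log2 above the Col-0 mean in jmj28-2 replicate 1 and at -0.56 in jmj28-2 replicate 2, and without replicate 2 the call was lost (adjusted p = 0.863, direction up). CASP2, a protein of the endodermal barrier, had 26.03 and 25.16 TPM in Col-0 and 22.93 and 16.43 TPM in jmj28-2, and MRN1, of root triterpene synthesis, 2.77 and 3.01 against 1.94 and 0.70 TPM. A total of 0 members passed over all genes or adjusted over the list alone. Iron homeostasis genes, many of them expressed in roots, had medians of 0.17 and -0.50 in the same 2 libraries and did not pass (camera adjusted p = 0.108). Their call was gained without jmj28-2 replicate 1 (adjusted p = 2.77e-05, direction down), and the direction turned up without jmj28-2 replicate 2 (adjusted p = 0.641). In FIT, their root regulator, levels were 9.89 ± 1.25 and 6.56 ± 1.52 TPM.

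Salicylic acid defence genes were higher in jmj28-2 (16 of 18 tested, median log2 change 0.34, camera adjusted p = 0.00255), and so were jasmonate genes (19 of 23, median 0.19, adjusted p = 0.0309). Both calls were lost with an estimated correlation (adjusted p = 0.828 for each). CBP60G, a regulator of salicylic acid synthesis, had 3.36 ± 0.495 and 7.19 ± 2.67 TPM, and PR5, a pathogenesis-related gene, 11.1 ± 0.191 and 16.3 ± 3.26 TPM. JAZ1, a repressor of jasmonate signalling, had 20.4 ± 3.22 and 29.3 ± 3.49 TPM, and the transcription factor MYC2 14.9 ± 2.02 and 20.2 ± 1.65 TPM. Not all members rose, with 2 salicylic acid and 4 jasmonate genes lower. Among these, named after their values were seen, PR1 had 7.21 ± 0.693 TPM in Col-0 and 6.815 ± 3.02 TPM in jmj28-2. VSP1 had 19.2 ± 2.74 and 15.4 ± 3.31 TPM, and VSP2 107.4 ± 0.41 and 73.7 ± 24.3 TPM. In both lists 0 members passed over all genes or adjusted over the list alone. The calls were also lost without jmj28-2 replicate 2, the library with low root markers (adjusted p = 0.3 and 0.863, the latter with direction down), and the jasmonate call without Col-0 replicate 2 (0.237), with a mean of at least 5 TPM (0.437) and with a pseudocount of 0.01 (0.0517).

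Abscisic acid and dehydration genes were lower (16 of 17 tested, median log2 change -0.17, camera adjusted p = 0.000784; adjusted p = 0.828 with an estimated correlation). The 2 Col-0 libraries themselves differed by more than that, with a median of -0.23 for replicate 1 minus replicate 2. ABF3, a transcription factor of abscisic acid signalling, had 53.8 ± 2.85 and 43.5 ± 3.83 TPM. The protective protein gene LEA4-5 had 2.36 ± 0.509 and 0.995 ± 0.247 TPM, and the exception was RD26, a dehydration-induced NAC factor, at 9.63 ± 1.21 and 13.8 ± 0.785 TPM. Light-harvesting and Rubisco small-subunit genes were also lower (18 of 22, median -0.10, camera adjusted p = 0.000784, or 0.828 with an estimated correlation). RBCS2B had 6958 ± 300.1 TPM in Col-0 and 5536 ± 26.1 TPM in jmj28-2. The other small-subunit genes of the list, named after their values were seen, did not all fall. RBCS1A had 18504 and 19376 TPM, RBCS1B 3042 and 3129 TPM, and RBCS3B 19232 and 17991 TPM. In both lists 0 members passed over all genes or adjusted over the list alone. Both calls were lost without jmj28-2 replicate 1 (0.07 and 0.338), and the light-harvesting call under quantile normalization (0.56).

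**Figure D3:**
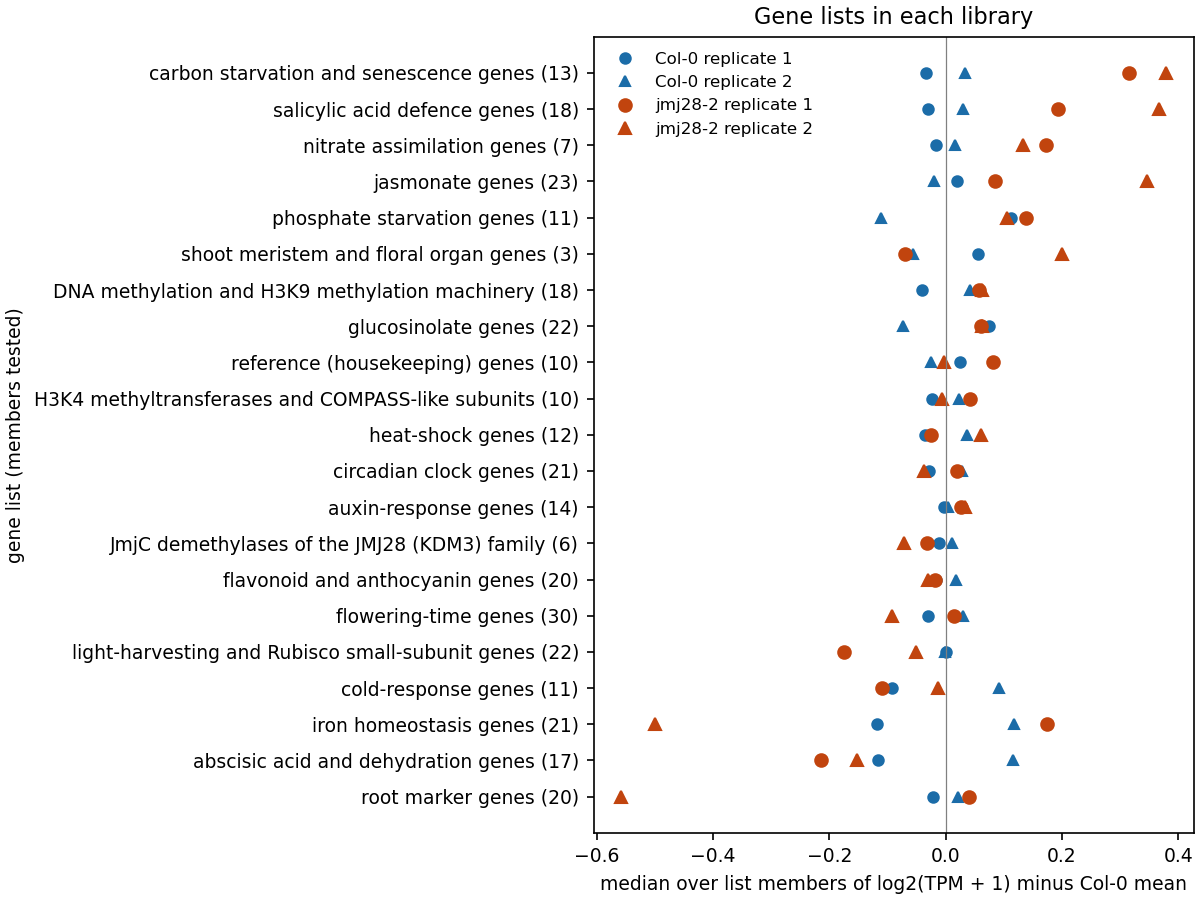
Median over the tested members of each gene list of log2(TPM + 1) minus the Col-0 mean, 1 point per library, with Col-0 in blue, jmj28-2 in red and the number of tested members in parentheses. The root markers lie at 0.04 and -0.56 in the jmj28-2 libraries, and the carbon starvation genes at 0.32 and 0.38.

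The remaining lists did not pass with camera, and 0 of their members passed over all genes with limma. Cold-response genes had 3 of 11 members higher (adjusted p = 0.204; 0.0405, direction down, without jmj28-2 replicate 2). COR6.6 and KIN1, which encode small cold-induced proteins, were lower in jmj28-2 and passed with limma adjusted over the list alone (adjusted p = 0.0344 and 0.035). They had 138.4 ± 3.2 against 114.1 ± 0.226 TPM and 70.0 ± 6.36 against 52.6 ± 3.98 TPM. The 3 higher members did not pass there but changed more, among them ZAT10 at 17.0 ± 11.1 and 38.3 ± 7.86 TPM. The list's median log2 change was -0.16 and its mean 0.11. In the shoot meristem and floral organ list, 3 members were tested (adjusted p = 0.639), and SEP3, a floral MADS-box gene, passed adjusted over the list alone at 3.81 ± 0.262 and 6.35 ± 0.764 TPM (0.0146). In the lists that follow, 0 members passed adjusted over the list alone. Members of the DNA and H3K9 methylation machinery were higher in 12 of 18 cases (adjusted p = 0.889), with ROS1, a DNA demethylase, at 16.8 ± 0.99 and 14.1 ± 0.467 TPM; the median log2 change was 0.05 and the mean -0.02. H3K4 methyltransferases and their partners were higher in 7 of 10 (adjusted p = 0.982). Nitrate assimilation genes were higher in 5 of 7 (adjusted p = 0.389), with nitrate reductase NIA2 at 327.9 ± 1.37 and 392.2 ± 45.7 TPM. Glucosinolate genes were higher in 16 of 22 (adjusted p = 0.639), phosphate starvation genes in 7 of 11 (0.501), auxin-response genes in 7 of 14 (0.889), heat-shock genes in 6 of 12 (1.00), and flavonoid and anthocyanin genes in 8 of 20 (0.532). The 10 reference genes had a median log2 change of 0.03 (adjusted p = 0.656). Over all genes tested, the median log2 change was 0.03.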

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

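The genes left out for being listed at 0 throughout a genotype were chosen after the data were seen; the other settings were planned. The count of genes higher in jmj28-2, 8 as reported, was 5 with a pseudocount of 0.01, 4 without a filter, 3 without the trend, 29 with robust fitting and 0 with the genes listed at 0 left out; leaving out 1 library gave 0 to 10. The count of genes lower, 7 as reported, was 3 with a pseudocount of 0.01, 4 with a mean of at least 5 TPM, 14 with robust fitting and 0 with the genes listed at 0 left out; leaving out 1 library gave 0 to 7. With a 2-fold minimum the counts were 6 and 7. With the zeros left out limma gave 2764 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0701. Of the 15 called genes, 15 were shared with robust fitting, 13 with quantile normalization, and 2, 0, 2 and 3 when Col-0 replicate 1, Col-0 replicate 2, jmj28-2 replicate 1 or jmj28-2 replicate 2 was left out; in each of these fits the lone library is assumed to vary like the other genotype. The cause of these shifts was not tested, apart from the fewer libraries or genes that a setting leaves.

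With the replicate block, 12 genes were higher and 6 lower, 9 of the 18 shared with the reported calls, and 7 lists passed, the seventh being iron homeostasis (adjusted p = 0.0449, direction down). Replicate 1 minus replicate 2 differences of the 2 genotypes correlated at 0.0162 across genes, so no replicate effect was seen over all genes together. A correlation over all genes cannot exclude such an effect in particular groups of genes. The count of lists, 6 as reported, was 0 with an estimated correlation and 0 with fry (10 by its mixed test), 6 with camera on ranks, all 6 shared with the reported ones, and 4 to 6 when 1 library was left out. JMJ28 stayed lower throughout, with an adjusted p of 0.212 to 0.79.

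Log2 changes near 0 turned sign for JMJ26 under median-ratio rescaling (-0.024) and quantile normalization (-0.003), and when 1 library was left out for ATXR3 (range -0.13 to 0.005), BHLH103 (-0.188 to 0.312), IBM1 (-0.049 to 0.037), JMJ24 (-0.09 to 0.033), JMJ26 (-0.059 to 0.063), JMJ27 (-0.078 to 0.032), PRR7 (-0.037 to 0.028), PUB8 (-0.018 to 0.202) and STM (-0.089 to 0.22). These genes were called in no setting. Of 1434 values of 112 named genes, 1328 kept direction and side of the threshold, 85 lost the call, 5 gained it and 16 turned sign. Only the 15 genes called as reported could lose a call. Most of the 1434 values belong to genes that were not called, so the 1328 do not measure how stable the calls were. Rescaling moved the median of all genes from 0.03 to -0.003 and -0.0047. Depth is unknown, so its limit on low genes cannot be given.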

Other observations

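The gene families, the neighbour-run, far-side and root-marker tests, the set of kinase genes and the clock-list index were chosen after results had been seen; the tests on other pairings of the libraries and on held-out rhythmic genes were set before theirs were. Cytosolic ribosomal protein genes, picked by their descriptions among 12 families, were higher in jmj28-2 in 181 of 187 cases, with a median log2 change of 0.18 and medians of 0.20 and 0.16 in the 2 jmj28-2 libraries (camera adjusted p = 1.42e-15; adjusted p = 0.523 with an estimated correlation). By limma, 0 of them passed over all genes, and 93 were higher at an unadjusted p under 0.05. In the other 2 pairings of the libraries the family's median was -0.07 and -0.03, and it passed there too (camera adjusted p = 0.000729 and 0.00542). Proteasome subunits were higher in 21 of 22 cases without passing (adjusted p = 0.0837).

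Photosystem subunit genes were lower as a group, with 4 of 27 higher and a median log2 change of -0.11 (camera adjusted p = 0.000485; adjusted p = 0.523 with an estimated correlation). They also passed when replicates 1 were set against replicates 2, with 20 of 27 higher and a median of 0.07 (adjusted p = 0.000729), though not in the crossed pairing (0.989). WRKY transcription factors were higher in 23 of 36 (median 0.17, adjusted p = 0.0186), and expansins, proteins of cell wall loosening, were higher in 8 of 21 (median -0.14, adjusted p = 0.0291). With an estimated correlation the camera adjusted p of both was 0.523, and neither passed in the other 2 pairings (0.764 and 0.99 for WRKY factors, 0.764 and 0.814 for expansins). A genotype difference adds to the spread within those pairs, so this does not show that the families depend on genotype. The other families did not pass with camera: calmodulins 39 of 50 higher (adjusted p = 0.0503), histones 24 of 34 (0.233), xyloglucan endotransglucosylases 17 of 26 (0.233), ethylene-responsive factors 34 of 53 (0.243), glutathione S-transferases 17 of 39 (0.301), kinases with the full description cysteine-rich receptor-like 11 of 15 (0.319) and tubulins 11 of 15 (0.551). Those 15 kinases had a median of 0.28 and included CRK28 and CRK29, both listed at 0 in jmj28-2. The family was not tested without these 2 genes, so its result does not describe the other members. Xyloglucan endotransglucosylases passed with replicates 1 set against replicates 2, with 6 of 26 higher and a median of -0.15 (camera adjusted p = 0.00134).

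The 4 genes beside JMJ28 at 0 in both jmj28-2 libraries form the longest such run among 19162 expressed genes, of which 15 were at 0 there and the next longest run was 1. Failed estimates scattered independently over the genome are argued against as the cause, since 0 of 100000 permutations gave a run as long (permutation p = 1e-05, the smallest they can give), but joint failures among neighbouring kinases that share reads are not. Reassignment of reads stays open for CRK28 and CRK29, which lost 15.98 TPM. The other 39 cysteine-rich receptor-like kinases named CRK gained 47.49 TPM in sum (2 standard errors, 5.63). The gain was larger than the loss and uneven between genes. Named after their values were seen, CRK10 and CRK40 gained 10 and 6.18 TPM, while CRK25 and CRK27 changed by -1.38 and -0.61 TPM. TPM cannot show where the gain came from, and SD18 and B120 were not covered. A lesion of the allele that reaches its neighbours, a linked stretch from another strain and an effect of JMJ28 on the cluster cannot be told apart without reads. The lowest ratio on the far side was 0.939, and JMJ28 stood at 0.729 of its Col-0 level. Beyond the run, AT4G21366, under the filter, was listed at 0 in Col-0 and at 1.23 and 1.11 TPM in jmj28-2. PUB8 and BHLH103 stood at 1.08 and 1.06, and ATSBT3.12 beyond them at 0.208. A loss confined to the run does not by itself account for the values of AT4G21366 and ATSBT3.12. These single genes do not decide between the causes, so the run is a hypothesis to check in genomic reads of the mutant.

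Of the lists past the threshold, 6 passed with the genotypes and 6 in each of the other 2 pairings, which is consistent with list genes that vary together between libraries whatever the genotype. Root markers, salicylic acid defence, abscisic acid, light-harvesting and jasmonate genes passed in at least 1 other pairing, and carbon starvation genes in neither, while iron homeostasis, cold-response, glucosinolate and phosphate starvation genes passed only in other pairings. Because a genotype difference adds to the spread within those pairs, a list that does not pass there is not thereby shown to depend on genotype. For root markers, the median of 0.04 in jmj28-2 replicate 1 (SD between markers, 0.251) and of -0.56 in replicate 2 leave a genotype effect open, since the share of root in each library is unknown. Less root material in replicate 2, or loss of particular root parts, also stays open: 19 of 20 markers were lowest in that library, but the markers had been seen to be low there before they were counted.

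In the clock list, 8 of 9 morning genes were lower and 7 of 8 midday to evening genes higher in jmj28-2, with mean log2 changes of -0.26 and 0.18. These classes were set after values had been seen and leave out 4 of the 21 tested clock genes, PRR7 (log2 change -0.004) among them, so the tally describes the chosen genes and tests nothing. The evening-minus-morning index was 0.037 and -0.037 in Col-0 and 0.384 and 0.496 in jmj28-2, a difference between genotypes 3.93 times the larger one within a genotype, which rests on the same chosen genes and leaves phase differences between single libraries open. In 6 held-out rhythmic genes outside the lists (morning CAT2, EPR1 and RVE2, evening GRP7, GRP8 and CAT3) the difference was 0.246 in the same direction without separating the classes (exact permutation, two-sided p = 0.3, smallest possible 0.1), and their index was 0.059 and 0.432 in the jmj28-2 libraries. A difference in clock phase between the genotypes' libraries may underlie the pattern, but the held-out genes leave that open. Its direction cannot be given, because no label gives the hour of harvest. For the same reason, the hour of harvest and the clock itself cannot be told apart as its source.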
